A study of Homo sapiens with 81 samples.

How the data were processed

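The series holds 81 poly(A) RNA sequencing libraries of human vastus lateralis biopsies, 3 from each of 27 participants: 1 before training and 1 from each leg after 10 weeks of training with 1 or 4 sets. The deposited file is a table of raw counts per gene, with 65217 Ensembl gene identifiers. Per the submitters' processing notes, the authors used fastp, STAR, featureCounts and the GRCh38 build; versions, the annotation release and the strand setting are not given in the sources used here, and the build in those notes is taken as that of the counts. Library totals were 19767000 to 31127000 counts, and the 81 columns were matched to samples by their titles, with no column left over. The spread of the differences within participants sets the precision of the comparisons.

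Gene places and types came from GENCODE release 29 on GRCh38, and symbols from a table of gene names that matched 56322 identifiers. The 8404 identifiers without a place in that annotation, which hold 4.36% of counts, and 515 rows on chromosome Y or for XIST and TSIX were left out, which left 56298 rows; 19088 rows of the table have no count in any library. Of the near-identical rows for ribosomal RNA, 3 hold counts within 0.11% of each other in every library and 1.64% of all counts each, so reads that map to several places appear to have been counted at each. Values of close paralogs, such as the myosin heavy chains, and of overlapping or antisense genes are uncertain for that reason. One fast myosin light chain gene of the fast fibre list is not analysed here.

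Groups came from the labels for the number of sets and the time of the biopsy, and participants from the number in the sample titles, which the labels give to all 3 biopsies of a person. As a check of the pairing, deviations from the group means were correlated between libraries of 1 participant: the median r was 0.36 for baseline with 1 set, 0.39 for baseline with 4 sets and 0.45 for 1 set with 4 sets, all 27 pairs were over 0.1 in each, and the consensus correlation was 0.342. Libraries of different participants were not correlated, so these r values have no reference and cannot show that each pair was matched rightly. The participant was kept as a block, as the within-subject design asks.

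Counts were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 16463 genes, scaled with TMM and tested with edgeR 4.0.16's quasi-likelihood test (robust options, group means plus participant) in R 4.3.3; the 3 contrasts were 1 set against baseline, 4 sets against baseline and 4 sets against 1 set, adjusted by Benjamini-Hochberg and called at 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. Gene lists, 42 in 9 kinds, were fixed before the data were examined; 41 with at least 5 genes tested entered camera (limma 3.58.1, preset correlation 0.01), and the list of red blood cell markers did not, as too few of its genes passed the filter. Camera with an estimated correlation and fry stand beside it. As an addition made after seeing the data, the mean log2 CPM (prior count 2) of each list was compared within participants by a sign-flip permutation test with 100000 resamples. Shares of counts in myosin, mitochondrial, haemoglobin and the 10 most abundant genes were compared in the same way, adjusted over 9 tests for myosin and 9 for the others.

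Named genes followed a rule fixed before the data were examined: per comparison the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 2 CPM that moved the called way in at least 20 of 27 participants, or all called genes above 2 CPM where fewer than 16 passed; up to 4 members with the lowest p of each list described; and 16 fixed genes in every comparison, all of which were tested. Any other gene named was chosen after its values were seen.

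The tests were checked on simulated counts for the real genes, with 50 genes changed at each of 4 sizes in the 4-set libraries and 16334 genes left after filtering. For 4 sets against baseline, 52% of genes with a 1.15-fold change were called, 84% at 1.3-fold, 96% at 1.5-fold and 100% at 2-fold, and 12 of 16109 unchanged genes; for 4 sets against 1 set the shares were 40%, 80%, 96% and 100%, and 6 unchanged genes were called. No gene was called for 1 set against baseline, where none had been changed. A list of 25 genes raised 1.1-fold in the 4-set libraries was called in both comparisons that involve them and none of 40 unchanged lists was. Simulated genes vary independently, unlike those of a biopsy. The sign-flip test gave a p below 0.05 in 40 of 40 simulated sets of 27 pairs with a shift of 1 SD. With no shift it did so in 1 of 40. Shifts below 1 SD, such as those of the myosin shares, were not simulated.

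Alternatives were DESeq2 size factors, library size alone, no low-count filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom and limma-trend, the participant as a random effect or left out, only the 2 groups compared, a term for the prefix of the sample titles, an adjusted p of 0.01, each participant left out in turn, and the fit without the 5 participants who gave any of the 5 libraries that stood apart (median Spearman rho with the other libraries more than 3 median absolute deviations below the median). Added after seeing the data were all rows of the table, protein-coding genes only and edgeR without its robust options. Figures were drawn with matplotlib 3.10.9 from Python 3.11.15.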

Results

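Gene expression was measured by RNA sequencing in biopsies of the vastus lateralis, a muscle of the thigh, from 27 older adults who trained their legs separately. Each participant trained 1 leg with 1 set of knee extension per session and the other leg with 4 sets, 2 times a week for 10 weeks, at loads that allowed 8 to 15 repetitions. A baseline biopsy was taken from 1 leg before training, and both legs were sampled 48 hours after the last session. The count table holds 81 libraries, 27 each for baseline, the 1-set leg and the 4-set leg, with total counts of 19767000 to 31127000 and group medians of 24232000, 23885000 and 24531000. After filtering, 16463 genes were tested. The leg that gave the baseline biopsy and the growth of each leg are not in the labels used here, so neither enters a comparison. The series is titled as a within-subject comparison of both training volumes, and the questions addressed are how each volume changed the muscle transcriptome and whether the legs differed.

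The myosin heavy chain genes, which encode the motor proteins that distinguish slow from fast muscle fibres, shifted away from the fastest isoform in the 4-set leg. MYH1, the type IIx isoform (chromosome 17, 10492307 to 10518543, GRCh38), held 15.1% ± 10.5 of the summed MYH7, MYH2 and MYH1 counts at baseline, 12.1% ± 8.43 in the 1-set leg and 9.59% ± 6.30 in the 4-set leg (mean ± SD, n = 27 each). With 4 sets its share dropped by 5.55 percentage points (SD of the paired differences 8.53) and was lower in 20 of 27 participants (two-sided sign-flip permutation test, adjusted p = 0.0157 over 9 tests). MYH2, the type IIa isoform, rose by 5.18 points with 4 sets (SD 9.78, higher in 17 of 27, adjusted p = 0.0451), from 33.4% to 38.6%. With 1 set the MYH1 share differed from baseline by -3.07 points (SD 6.55, lower in 18 of 27, adjusted p = 0.0653). The direct difference between the legs in the MYH1 share was -2.48 points (SD 7.01, adjusted p = 0.14). MYH7, the slow isoform, differed from baseline by 1.62 points (SE 2.26) with 1 set and 0.363 points (SE 1.93) with 4 sets, with adjusted p of 0.618 and 0.852. Without the 5 participants who gave a library that stood apart from the rest, the 4-set difference in MYH1 was -5.54 points but no longer passed (adjusted p = 0.0616), and that in MYH2 was 4.33 points (adjusted p = 0.207). Tested without pairing, the MYH1 and MYH2 differences of -5.55 and 5.18 points both had an adjusted p of 0.183. Reads shared between these near-identical genes could move counts between them.

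**Figure D1:**
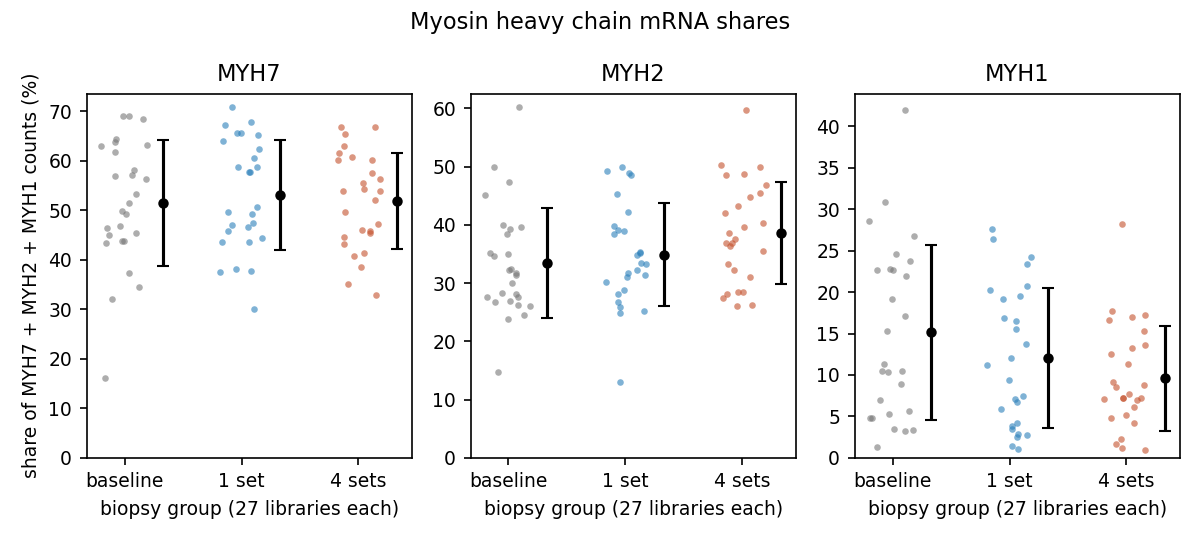
Share of the summed MYH7, MYH2 and MYH1 counts held by each gene (y axis, percent) in the 27 libraries of each group (x axis); each coloured point is 1 library and black points with bars are the mean ± SD. Mean MYH1 shares were 15.1% at baseline, 12.1% with 1 set and 9.59% with 4 sets, with wide spread in each group.

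The 13 mitochondrially encoded mRNAs took 12.2% of all counts at baseline, 13.3% in the 1-set leg and 13.6% in the 4-set leg. The rise with 4 sets was 1.40 points (SD 2.34, higher in 20 of 27, sign-flip permutation adjusted p = 0.0403). With 1 set the difference was 1.16 points (SD 2.24, higher in 20 of 27, adjusted p = 0.0554). On a log2 scale the 4-set rise was 0.15 with an adjusted p of 0.0506, and without pairing its adjusted p was 0.153. Haemoglobin genes, a sign of blood in the biopsy, held 0.0403%, 0.0378% and 0.0462% of counts in the groups, and no comparison passed (adjusted p of 0.873 in each).

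With 4 sets, 9 of 23 glycolysis genes rose, as did 12 of 39 nuclear genes of oxidative phosphorylation, and 6 of 19 immediate early genes fell. In edgeR's quasi-likelihood test with the participant as a block and Benjamini-Hochberg adjustment, 544 of 16463 genes differed from baseline, 231 higher and 313 lower, 503 of them protein-coding. Most changes were small: the median absolute log2 fold change was 0.19, and 39 genes changed 1.5-fold or more. Among the largest rises were CA14, a membrane carbonic anhydrase (log2 fold change 1.13 ± 0.18 SE, adjusted p = 9.6e-05, higher in 23 of 27 participants), NMRK2, a nicotinamide riboside kinase of the NAD salvage pathway (0.94 ± 0.11, adjusted p = 7.1e-07, higher in 24), and SLC16A3, the lactate exporter MCT4 (0.93 ± 0.15, adjusted p = 0.000191, higher in 25). NMRK2, on chromosome 19 from 3933103 to 3942416 (GRCh38), went from 90.4 ± 36.6 CPM (counts scaled to library size, mean ± SD) at baseline to 189 ± 108 in the 4-set leg. The matrix genes MXRA5 (0.92), LAMB3, a laminin chain (0.61), and COL4A1, a basement membrane collagen (0.60), and also IRX3 (0.72) and NETO2 (0.65), completed the 8 largest rises under the same rule for named genes, with adjusted p between 1.7e-05 and 0.0371.

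Among called protein-coding genes of at least 2 CPM that were lower in at least 20 of 27 participants, the 8 largest falls with 4 sets were METTL21C, a lysine methyltransferase of muscle (-1.06 ± 0.26), OTUD1, a deubiquitinase (-0.97 ± 0.27), the nuclear receptors NR4A1 (-0.76 ± 0.17) and NR4A2 (-0.70 ± 0.21), the antiproliferative gene BTG2 (-0.71 ± 0.20), the cytokine IL32 (-0.68 ± 0.20), MYH1 (-0.66 ± 0.19) and CRYM (-0.66 ± 0.19), with adjusted p between 0.00638 and 0.0471. Of the genes fixed for every comparison, PPARGC1A, a coactivator of mitochondrial biogenesis, rose by 0.32 ± 0.09 (adjusted p = 0.0254), and TRIM63, the muscle ubiquitin ligase MuRF1, fell by 0.35 ± 0.10 on the log2 scale (adjusted p = 0.0368, lower in 18 of 27). COL1A1 (0.33), COL3A1 (0.42), MYH7 (-0.04), MYH2 (0.16), MYH3 (0.06), MYH8 (0.06), PAX7 (0.02), MYOG (0.02), MSTN (-0.27), FBXO32 (-0.01), MYC (-0.31) and IGF1 (-0.24) did not pass. Without the participants of libraries that stood apart, LAMB3, OTUD1, NR4A1, NR4A2, BTG2, MYH1, CRYM and TRIM63 no longer passed, with adjusted p between 0.0724 and 0.291. A fit without the participant block called 9 genes.

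**Figure D2:**
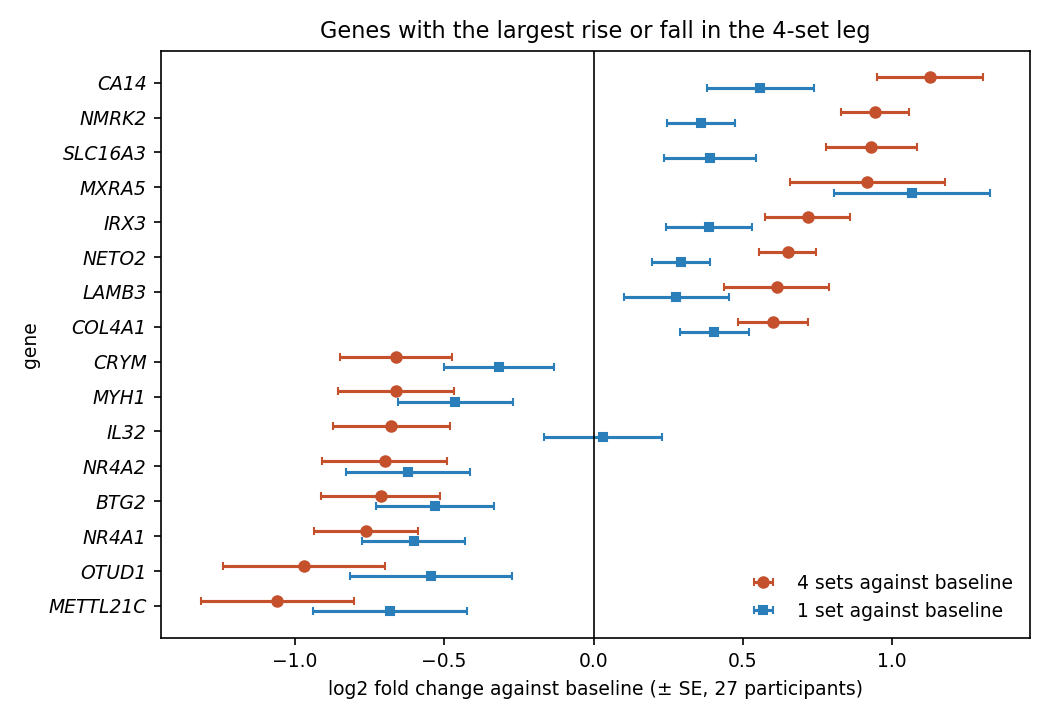
Log2 fold change against baseline (x axis, ± SE over 27 participants) of the 16 genes with the largest rise or fall in the 4-set leg under the rule for named genes (y axis), for the 4-set leg (red circles) and the 1-set leg (blue squares). All but MXRA5 lie closer to 0 with 1 set, which their selection by the 4-set values favours. IL32 lies at 0.03 with 1 set against -0.68 with 4 sets, and it did not pass between the legs (edgeR adjusted p = 0.20).

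Of the 41 gene lists tested with camera at a preset correlation, 12 were higher and 9 lower with 4 sets than at baseline. Of these 21 lists, 12 were called in the same direction by fry and 1 with an estimated correlation. In the glycolysis and glycogen list, 9 of 23 genes rose and none fell (12 rose when adjusted over the list alone), with a median log2 fold change of 0.13 (camera adjusted p = 2.2e-14). PKM, the last enzyme of glycolysis (0.45 ± 0.06, adjusted p = 7.1e-07), TPI1 (0.29 ± 0.05), GPI (0.20 ± 0.04) and PGK1 (0.20 ± 0.04) had the lowest p. The mean of this list was higher in 26 of 27 participants, and it was the only list whose call held with an estimated correlation (adjusted p = 0.0266). Of the 39 nuclear genes of oxidative phosphorylation, 12 rose (25 adjusted over the list alone; median 0.12; camera adjusted p = 2.1e-17; adjusted p = 0.174 with an estimated correlation), led by the ATP synthase subunits ATP5F1C (0.19), ATP5MC3 (0.22) and ATP5F1B (0.17). The tricarboxylic acid cycle list had 4 of 20 genes higher (15 adjusted over the list alone; median 0.11; adjusted p = 0.174 with an estimated correlation), among them PDHA1 (0.19) and PDHB (0.12) of pyruvate dehydrogenase and FH (0.11). Of the 13 mitochondrially encoded genes 2 rose, MT-CO3 (0.19) and MT-ND6 (0.23), and 7 when adjusted over the list alone (median 0.17; adjusted p = 0.244 with an estimated correlation). Leaving out the 5 participants of libraries that stood apart, all 13 passed adjusted over the list alone (median 0.25).

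Basement membrane genes were higher as a list with 4 sets (median 0.15, camera adjusted p = 3.2e-05): COL4A1 (0.60), COL4A2 (0.46) and LAMB1 (0.31) rose among 18, or 6 higher and 1 lower when adjusted over the list alone, with an adjusted p of 0.294 with an estimated correlation. The median was 0.09 without the 5 participants of libraries that stood apart. Angiogenic signalling genes (median 0.08) included rises of VEGFB (0.23) and the Notch ligand DLL4 (0.39) among 21, and 3 adjusted over the list alone. Endothelial markers (median 0.09) included rises of the junction proteins CLDN5 (0.38) and PECAM1 (0.30) among 13, and 4 adjusted over the list alone. The adjusted p with an estimated correlation was 0.174 for the angiogenic and 0.294 for the endothelial list. The interferon list (median 0.11), fatty acid uptake and oxidation (0.06, with UCP3 called at 0.38), fibrillar collagens (0.16), mitochondrial biogenesis (0.04) and markers of T, B and natural killer cells (0.14) were also higher by camera, with adjusted p of 0.314 to 0.633 with an estimated correlation. The collagen and the lymphocyte calls were lost without the 5 participants of libraries that stood apart, with camera adjusted p of 0.321 and 0.184. In that fit 2 endothelial markers and 3 fatty acid genes passed adjusted over the list alone, in place of 4 and 1, 1 interferon gene passed in place of 0, and the median of mitochondrial biogenesis was 0.06.

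Among the lists that were lower with 4 sets, immediate early genes, which respond within minutes to contraction and stress, had the lowest median, -0.39: 6 of 19 fell (12 adjusted over the list alone), with KLF4 at -0.65 ± 0.11 (adjusted p = 9.6e-05), JUND at -0.39 ± 0.08, NR4A1 at -0.76 and NR4A3 at -1.56 ± 0.42. The camera adjusted p was 1.3e-08, and the adjusted p was 0.119 with an estimated correlation. The median was -0.27 without the 5 participants of libraries that stood apart, and 3 genes were lower adjusted over the list alone. Sarcomere stress genes (median -0.15) had 7 of 22 members lower and 10 adjusted over the list alone, including HSPB1 (-0.37), KLHL40 (-0.41), XIRP1 (-0.65) and CRYAB (-0.23). Heat shock genes (median -0.10) had 4 of 20 lower and 1 higher, or 10 and 1 adjusted over the list alone, including HSPA5 (-0.15) and DNAJB4 (-0.25). Of 28 proteasome subunits 6 fell (12 adjusted over the list alone; median -0.08), by 0.15 on the log2 scale for PSMD4 and less for the others. Of 46 ribosomal proteins RPL30 (-0.13) and RPL10A (-0.11) fell, or 8 adjusted over the list alone (median -0.07). The autophagy list (median -0.05) had 3 of 22 lower, SQSTM1 (-0.18), CTSD (-0.16) and GABARAPL1 (-0.25), and 5 adjusted over the list alone. TRIM63 and TRIM54 (-0.13) fell among the 22 ubiquitin ligase and atrophy genes (median -0.09; 2 adjusted over the list alone). With an estimated correlation the adjusted p of these 6 lists lay between 0.119 and 0.294, and by fry between 0.00107 and 0.0429. The complement (median -0.12) and circadian (median -0.18) lists were lower by camera with an adjusted p of 0.457 and 0.294 with an estimated correlation. By fry those lists did not pass (adjusted p = 0.181 and 0.0703). The circadian call was lost without the 5 participants of libraries that stood apart (median -0.13, camera adjusted p = 0.205), and the autophagy list then had a median of -0.03 and 3 genes lower adjusted over the list alone.

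Some fixed lists went both ways or did not pass with 4 sets. In the fast fibre list, ACTN3 (-0.48), MYLK2 (-0.36), ATP2A1 (-0.22) and MYH1 fell, whereas LDHA (0.28), ENO3 (0.27) and MYL1 (0.16) rose, and 6 were higher and 9 lower of 19 adjusted over the list alone (camera adjusted p = 0.221). Satellite cell genes (median 0.02, adjusted p = 0.45), developmental sarcomere isoforms (-0.05, adjusted p = 0.45), the slow fibre list (-0.06, adjusted p = 0.0533), fibroblast markers (-0.07, adjusted p = 0.367) and pericyte markers (-0.07, adjusted p = 0.0608) did not pass. Neither did the lists of ribosome biogenesis (-0.03), mTORC1 signalling (-0.03), polyamine metabolism (-0.03), cell cycle (0.05), antigen presentation (0.05), cytokines (-0.02), p53 (-0.02), matricellular proteins (0.11) and the neuromuscular junction (-0.07), nor the markers of macrophages (0.12), granulocytes (0.11), adipocytes (0.04), Schwann cells (-0.04) and tendon (-0.12), all given as medians.

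With 1 set, 4 genes differed from baseline, each with an adjusted p of 0.0317 in edgeR's test. UCP2, a mitochondrial carrier, rose by 0.33 ± 0.06 and DOCK9 by 0.28 ± 0.06, in 20 and 23 of 27 participants. WBP2 fell by 0.17 ± 0.03 on the log2 scale (lower in 21) and LANCL1-AS1 by 0.39 ± 0.08 (lower in 22). The antisense gene LANCL1-AS1 cannot be told apart from its partner without strand information, and LANCL1 itself stood at 0.03 ± 0.04. At an unadjusted p below 0.05 there were 2262 genes, and DESeq2 called 141. If no gene changed, 823 would be expected on average, but genes that vary together can move that count widely. No gene passed without the 5 participants of libraries that stood apart, 4 of which were 1-set libraries, nor in a fit of only the 2 groups or with library size in place of TMM. Without the participant block 5 genes passed, none of them among these 4. Of the genes fixed for every comparison none passed. COL1A1 stood at 1.17 ± 0.33 (adjusted p = 0.104), COL3A1 at 0.92 ± 0.27 (0.116), COL4A1 at 0.40 ± 0.12 (0.105), MYH8 at 0.56 (0.449), MYH1 at -0.46 (0.267), TRIM63 at -0.31 (0.152), MSTN at -0.26 (0.30), MYH3 at 0.23 (0.676), IGF1 at 0.20 (0.70), MYOG at 0.19 (0.358), PPARGC1A at 0.11 (0.585), FBXO32 at -0.11 (0.607), MYC at 0.07 (0.868), PAX7 at 0.06 (0.814) and MYH2 and MYH7 at -0.02 (0.944 and 0.957), with adjusted p in parentheses.

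As lists, matrix genes were higher in the 1-set leg than at baseline. Fibrillar collagens and their processing enzymes had a median of 0.35, with 14 of 20 genes higher when adjusted over the list alone and none over all genes (camera adjusted p = 4.0e-11; adjusted p = 0.253 with an estimated correlation). COL5A2 (0.61 ± 0.16), LOX (0.64 ± 0.18), COL1A1 and COL3A1 had the lowest p, and the list's mean was higher in 20 of 27 participants (0.36 ± 0.12 SE, sign-flip permutation adjusted p = 0.0482). Without the 5 participants of libraries that stood apart this mean was 0.22 ± 0.09 and no longer passed (adjusted p = 0.121). Matricellular genes, among them ASPN (0.88) and SPARC (0.45), had a median of 0.36, with 15 of 23 higher adjusted over the list alone. Basement membrane genes, led by NID1 (0.31), had a median of 0.23, with 14 of 18 higher and 1 lower adjusted over the list alone. Fibroblast markers (median 0.20, all 16 above 0, none passing) and endothelial markers (median 0.12, 3 of 13 passing adjusted over the list alone) moved with them. The adjusted p of these 4 lists was 0.253 to 0.262 with an estimated correlation. Without the 5 participants of libraries that stood apart, the medians were 0.19 for collagens (6 genes adjusted over the list alone), 0.19 for matricellular genes (3), 0.18 for basement membrane (6), 0.11 for fibroblast markers (0) and 0.15 for endothelial markers (7). COL1A1 averaged 24.4 ± 11.7 CPM at baseline, 93.4 ± 164 in the 1-set leg and 39 ± 58.9 in the 4-set leg (mean ± SD).

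Ribosomal proteins were lower as a list with 1 set (median -0.07, 14 of 46 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.1e-12; adjusted p = 0.262 with an estimated correlation), with RPLP1 at -0.17 ± 0.04 and RPS25 at -0.16 ± 0.04. Sarcomere stress genes (median -0.13), proteasome subunits (-0.04), circadian genes (-0.19), the fast fibre list (-0.07), immediate early genes (-0.16) and ubiquitin ligases (-0.07) were lower too. The mitochondrially encoded genes (0.12), interferon genes (0.13), angiogenic signalling (0.10), glycolysis (0.05), cell cycle (0.07), complement (0.15), p53 (0.13) and the neuromuscular junction list (0.19) were higher, as were the markers of macrophages (0.17), granulocytes (0.19) and tendon (0.36), all given as medians. With an estimated correlation the smallest adjusted p among all lists in this comparison was 0.253. Of the 23 lists called, 13 were called in the same direction without the 5 participants. Among these, 23 ribosomal proteins were then lower and 12 mitochondrially encoded genes higher adjusted over the list alone, in place of 14 and 0. Glycolysis had 2 higher in place of 1, sarcomere stress genes 0 lower in place of 2, and the circadian median was -0.11. The lists for which the call ended were fast fibre, ubiquitin ligases, immediate early, p53, cell cycle, complement, interferon, and the macrophage, granulocyte and tendon markers, with camera adjusted p between 0.107 and 0.274. The nuclear genes of oxidative phosphorylation had a median of 0.01 and did not pass (adjusted p = 0.826), nor did the tricarboxylic acid cycle (0.02, adjusted p = 0.283). Calls gained without the 5 participants were the tricarboxylic acid cycle, higher (0.04, camera adjusted p = 0.0174), and heat shock genes, lower (-0.03, adjusted p = 0.0341).

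Between the legs, 6 genes differed in edgeR's test, 3 higher and 3 lower with 4 sets. NMRK2 (0.58 ± 0.11, 1.5-fold, higher in 24 of 27) and NAMPT, the rate-limiting enzyme of NAD salvage (0.27 ± 0.06, higher in 23), were higher in the 4-set leg, both with an adjusted p of 0.0324. FYB2 (0.78 ± 0.17, adjusted p = 0.0465) lay below the expression minimum for named genes at 1.64 CPM and is given because the count is small. KIAA0930 (-0.19 ± 0.04, adjusted p = 0.0324), the lysosomal membrane gene LAPTM4A (-0.13 ± 0.03, adjusted p = 0.0365) and MFAP4, a microfibril protein of the matrix (-0.50 ± 0.11, adjusted p = 0.0465), were lower with 4 sets, in 22, 21 and 22 of 27 participants. At an unadjusted p below 0.05 there were 1610 genes. The average would be 823 if no gene changed, with the same limit that genes vary together. With a term for the prefix that the sample titles give the trained legs, no gene passed. Of the prefixes, 17 of the 27 4-set libraries carry the prefix BD and 17 of the 27 1-set libraries carry BE. The labels used here do not say what they mean. Of these 6 genes only NAMPT passed without the 5 participants of libraries that stood apart (0.25, adjusted p = 0.0447).

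No gene fixed for every comparison differed between the legs in this direct test. The values were -0.84 for COL1A1, -0.50 for COL3A1 and MYH8, -0.44 for IGF1, -0.37 for MYC, 0.21 for PPARGC1A, 0.20 for COL4A1, -0.20 for MYH1, 0.18 for MYH2, -0.17 for MYH3 and MYOG, 0.10 for FBXO32, -0.04 for TRIM63 and PAX7, -0.02 for MYH7 and -0.01 for MSTN, with adjusted p of at least 0.335. As lists, 7 were higher and 12 lower with 4 sets. All 39 nuclear genes of oxidative phosphorylation lay above 0 (median 0.11, 24 passing adjusted over the list alone, camera adjusted p = 1.7e-24), led by CYCS, cytochrome c (0.22 ± 0.05). Glycolysis (0.10, 10 of 23 passing adjusted over the list alone) and the tricarboxylic acid cycle (0.09, 8 of 20) were also higher. All 16 fibroblast markers lay below 0 (median -0.28, 10 passing adjusted over the list alone), among them PDGFRA (-0.27 ± 0.07, lower in 25 of 27), CFD (-0.37) and FBLN1 (-0.41). All 17 complement genes lay below 0 (median -0.21, 6 passing adjusted over the list alone). No gene of these 5 lists passed adjusted over all genes, and adjustment over the list alone does not allow for the 41 lists tested. With an estimated correlation no list passed, and the adjusted p of the 5 lists lay between 0.121 and 0.181. Without the 5 participants of libraries that stood apart, the median of fibroblast markers was -0.18 (5 passing adjusted over the list alone). That of complement genes was -0.19 (5 passing), and that of matricellular genes was -0.18 in place of -0.28. Adjusted over the list alone, 4 glycolysis genes passed in place of 10 and 14 genes of the tricarboxylic acid cycle in place of 8. The test of each list's mean per participant called glycolysis (0.11 ± 0.03 SE, higher in 19 of 27, adjusted p = 0.0234) and immediate early genes (-0.21 ± 0.05, lower in 21 of 27, adjusted p = 0.00246). Without those participants glycolysis no longer passed (0.08 ± 0.03, adjusted p = 0.0515) and immediate early genes did (-0.17 ± 0.04, adjusted p = 0.00943). The lists that passed only then were nuclear oxidative phosphorylation (0.11, adjusted p = 0.0161), the tricarboxylic acid cycle (0.09, adjusted p = 0.0041), and the markers of lymphocytes (0.27, adjusted p = 0.0451) and tendon (-0.23, adjusted p = 0.0454).

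**Figure D3:**
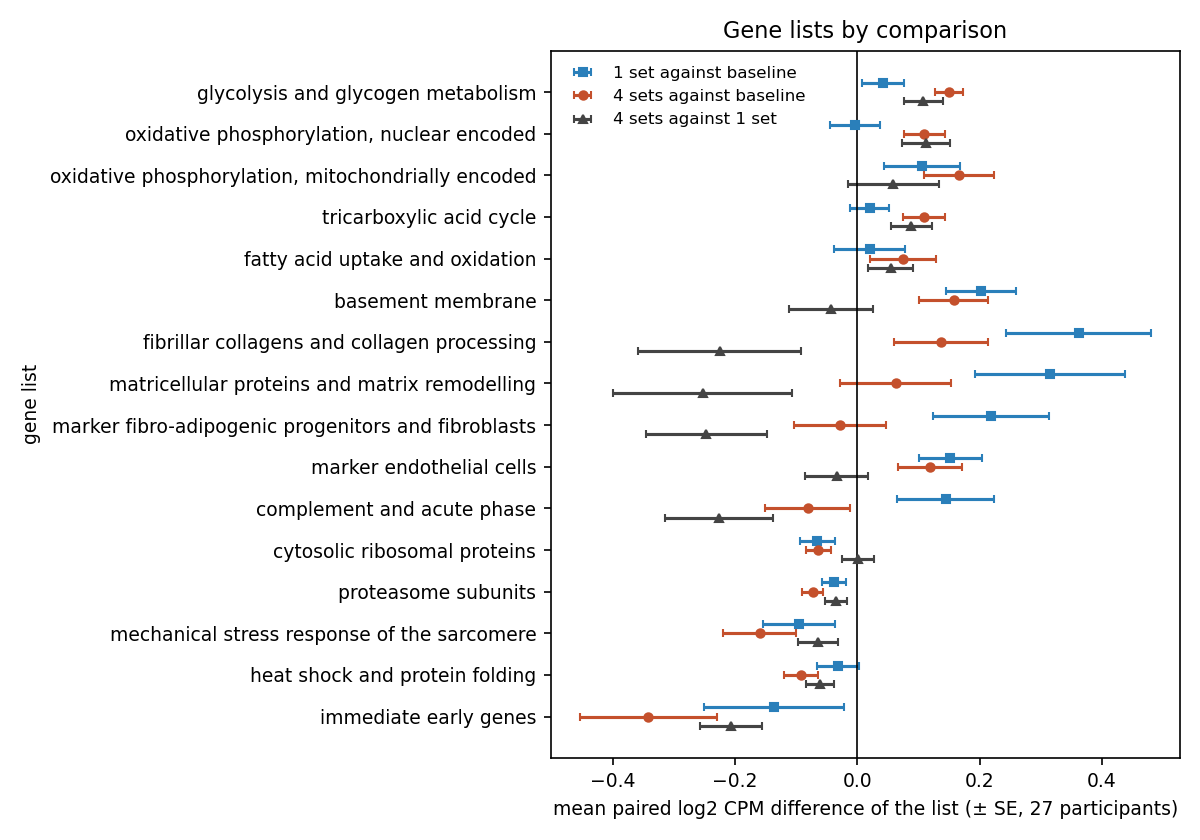
Mean paired difference in log2 CPM of 16 gene lists (x axis, ± SE over 27 participants; y axis, list) for the 1-set leg against baseline, the 4-set leg against baseline and the 4-set against the 1-set leg. Glycolysis stands at 0.15 with 4 sets and 0.04 with 1 set, and fibrillar collagens at 0.14 and 0.36.

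The responses of both legs were compared across genes. Of the 231 genes higher with 4 sets, 228 were above 0 with 1 set, and 226 of the 231 had a smaller fold change there. Of the 313 lower genes, 309 were below 0 with 1 set and 299 were smaller. These counts come from genes selected in the 4-set leg against the same baseline libraries, which moves both toward a shared direction and a smaller value. Across all 16463 genes the fold changes of both legs had r = 0.584 and a same-sign share of 71.7%; genes are not independent replicates. Unchanged groups, simulated with a simulated baseline that both legs share, gave r = 0.502 on average (highest of 20 simulations 0.525). Their same-sign share was 66.7%, beside r = 0.584 and 71.3% for the observed mean paired differences. The observed covariance was 0.0105 against 0.00553 simulated, which leaves 0.00494. Part of that may come from variation that both legs of a visit share, which the simulation does not hold. With the participants split so that the 1-set response came from 13 and the 4-set response from the other 14, r averaged 0.167 over 50 splits (0.0198 to 0.323) and the same-sign share 57.3%. Means of fewer participants are noisier, which lowers r. The covariance of the splits, in which no visit is shared, averaged 0.00481 (0.000576 to 0.00918), close to the 0.00494 left above. That average leaves little for variation that both legs of a visit share, but the splits ranged widely. Of the calls with 1 set, 1 of 2 higher and 2 of 2 lower genes were also called with 4 sets. Both comparisons share the baseline libraries, so some overlap is built in.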

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

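The tests on libraries that stood apart, on fibroblast RNA, on other cell types and on a visit difference were chosen only after the results were seen. The direct test between the legs set apart 6 genes and 19 lists, since there the response with 4 sets differed from that with 1 set. The genes were NMRK2 (0.58 on the log2 scale), NAMPT (0.27), FYB2 (0.78), KIAA0930 (-0.19), LAPTM4A (-0.13) and MFAP4 (-0.50). The lists higher with 4 sets, as median log2 fold changes, were nuclear oxidative phosphorylation (0.1065), mitochondrially encoded genes (0.0568), the tricarboxylic acid cycle (0.0909), fatty acid oxidation (0.0378), glycolysis (0.0986), mitochondrial biogenesis (0.0432) and lymphocyte markers (0.1895). The lower ones were fibrillar collagens (-0.20), matricellular genes (-0.28), the neuromuscular junction (-0.17), autophagy (-0.022), the proteasome (-0.0382), heat shock (-0.0774), immediate early genes (-0.18), p53 (-0.15), complement (-0.21), and the markers of pericytes (-0.11), fibroblasts (-0.28) and tendon (-0.15). None of the 19 held with an estimated correlation, where the smallest adjusted p was 0.121, and 7 held by fry. With a term for the prefix of the sample titles, 14 of the 19 were called in the same direction. Without the 5 participants of libraries that stood apart the autophagy call ended (camera adjusted p = 0.0791), and the medians moved to -0.177 for both matricellular genes and fibroblast markers, -0.0175 for the proteasome, -0.0489 for heat shock, -0.084 for p53 and -0.0853 for tendon markers. Calls gained in that fit were basement membrane, lower (-0.0792, camera adjusted p = 0.0168), and interferon genes, higher (0.066, adjusted p = 0.0456).

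Matrix genes were higher as lists in the 1-set legs than at baseline by camera with a preset correlation. With an estimated correlation the adjusted p was 0.253 for the collagen, basement membrane and matricellular lists. The mean paired difference of the collagen list was 0.362 (SE 0.118) with all participants and 0.22 (SE 0.0903, n = 22, higher in 15) without the 5 participants of libraries that stood apart, of which 4 were 1-set libraries. The sign-flip adjusted p over the lists was 0.0482 before and 0.121 after, so the call ended with a smaller mean and fewer participants. The mean stayed above 0 without those participants, but this test was chosen after the results were seen. The size of the rise rests partly on those libraries, and whether they account for all of it is not settled. More fibroblast RNA in the 1-set biopsies would raise fibroblast markers as much as collagens only if both were equally specific to fibroblasts. That was not tested. With all participants, the collagens exceeded the fibroblast markers outside the matrix lists by 0.154 (SE 0.0619), while those markers stood at 0.209. A larger fibroblast share may thus account for part of the rise, and this gap cannot tell whether it accounts for all. Matrix synthesis in response to training, and where each needle sampled the muscle, stay open and were not tested.

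Energy metabolism genes were higher as lists in the 4-set legs than at baseline by camera with a preset correlation. With an estimated correlation glycolysis held (adjusted p = 0.0266). Nuclear oxidative phosphorylation and the tricarboxylic acid cycle did not (adjusted p = 0.174 for both). By fry each passed, with adjusted p of 9.2e-05 for glycolysis, 0.0134 for nuclear oxidative phosphorylation and 0.00957 for the tricarboxylic acid cycle. Less RNA of other cell types would lower the markers of every such type if expression per cell stayed the same. Endothelial markers were higher by 0.119 (SE 0.0522, higher in 19 of 27), and macrophage markers stood at 0.1155 (SE 0.0891). Pericyte markers stood at -0.0944 (SE 0.0411), and fibroblast markers at -0.0284 (SE 0.0747). The markers thus did not all fall. As they cannot separate the number of cells from expression per cell, dilution is not excluded, and a change in fewer cell types stays open. Transcript length was tested with 10000 lists matched on length and expression: the median of the 81 energy genes, 0.1161, lay above all of them (median -0.0368, highest -0.00223). A training response of muscle fibres and a change of fibre types may both contribute, and the design does not separate them.

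Immediate early and clock genes were lower as lists in the trained legs by camera with a preset correlation; with an estimated correlation the adjusted p was 0.43 and 0.119 for immediate early genes and 0.253 and 0.294 for clock genes, with 1 and 4 sets. By fry the adjusted p was 0.222 and 0.00298 for immediate early genes and 0.0537 and 0.0703 for clock genes, with 1 and 4 sets. Without the 5 participants of libraries that stood apart, the immediate early call with 1 set and the clock call with 4 sets ended (camera adjusted p of 0.115 and 0.205). A difference between the visits that both legs share would leave the legs alike, yet the immediate early list was lower with 4 sets than with 1 set by a mean paired difference of -0.206 (SE 0.0508, lower in 21 of 27, sign-flip permutation p = 6e-05). Such a difference alone thus does not account for the further fall of immediate early genes with 4 sets. It stays open for their fall with 1 set, for the rest of their fall with 4 sets and for the clock genes. The clock list did not pass between the legs (median 0.03, camera adjusted p = 0.597). The order in which the legs were sampled is not in the labels and stays open. For the clock genes, the time of day cannot be told apart from training: the PER and NR1D arm minus the BMAL1 arm differed from baseline by -0.286 (SE 0.334) with 4 sets, and the spread between participants is wider than any shift of the group.

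Splits that swapped the groups within 13 of the 27 participants were run 100 times for each count, the real split included. They used limma-trend for genes and camera on log2 CPM for lists, and the real counts below come from these tests. The main tests called 4, 544 and 6 genes and 23, 21 and 19 lists. For genes, 3 splits gave as many as the real 4 with 1 set (highest other 83), 1 gave as many as the real 542 with 4 sets (highest other 6), and 2 gave as many as the real 5 between the legs (highest other 52). For lists, 1 split gave as many as the real 22 with 1 set (highest other 21), 2 gave as many as the real 19 with 4 sets (highest other 19), and 4 gave as many as the real 19 between the legs (highest other 22). No other split came near the 542 genes with 4 sets, and 1 of 100 is the smallest share these splits can give. This bears on the number of calls and not on single genes, and it does not separate training from the visit. The other 5 shares were also under 0.05, without allowance for 6 tests, and other splits came close or gave more. The splits that called 83 and 52 genes may point to a structure of the samples or to genes that vary together, and neither was tested. The median split called 8 or 9 lists, so camera with a preset correlation calls lists in unrelated splits too.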

How the results depend on the processing

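All rows of the table, protein-coding genes, edgeR without robust options and list means were chosen after seeing the data. With 4 sets, 544 genes differed from baseline and the counts lay between 383 (limma-voom, participant random) and 781 (DESeq2), except 176 at an adjusted p of 0.01 and 9 without the participant block, which leaves the spread between participants in the error; leaving out 1 participant gave 365 to 637, with 283 of the 544 kept in every such fit. With 1 set (4 genes) the counts were 0 at an adjusted p of 0.01, with library size only, without the participants of libraries that stood apart and with only the 2 groups compared, 635 with no low-count filter, 10 at a mean CPM of at least 1, 9 with the title prefix, 7 for protein-coding genes, 8 without robust options, 26 and 1 with limma-voom (participant fixed and random), 141 with DESeq2, and 0 to 51 leaving out 1 participant. Between the legs (6 genes) they were 0 at an adjusted p of 0.01, with library size only, without the participant block and with the title prefix, 428 with no low-count filter, 2 without the participants of libraries that stood apart, 10 with only the 2 groups, 3 with limma-voom (random), 38 with DESeq2, and 0 to 34 leaving out 1 participant. Of the 6 genes themselves, 5 were called with no low-count filter and 1 without those participants. Only 4 were called with only the 2 groups, 2 with limma-voom (random) and 2 with DESeq2. Without the filter 44230 genes entered, and only 18, 4 and 6 of the calls lay outside the 16463 genes; the median prior degrees of freedom, 10.5 with the filter, became infinite, and 334 of the 544 calls were kept. Apart from the block, the cause was not tested. Lists called with 1 set (23) were 15 without those participants, 0 with an estimated correlation, 0 with fry and 2 by list means; with 4 sets (21), 1, 13 and 13 by the last 3; between the legs (19), 0, 7 and 2. With the title prefix, 19 of the 23 list calls with 1 set were kept, 20 of the 21 with 4 sets and 14 of the 19 between the legs. No list was called in the opposite direction with the other scalings, the filter at a mean CPM of 1, no participant block, the title prefix, without those participants, an estimated correlation or fry. Without pairing (the participant block), the 4-set differences in the shares of MYH2 (5.18), MYH1 (-5.55) and mitochondrial mRNA (1.40) no longer passed, nor did MYH2 (4.33) and MYH1 (-5.54) without the participants of libraries that stood apart, or the mitochondrial share on a log2 scale (0.15). Among differences that did not pass, those that moved were MYH7 between the legs (0.182 without those participants) and haemoglobin on a log2 scale (0.0741 with 1 set, -0.0134 between the legs). The likeness of both responses was 0.934 over genes past the threshold in either, a value raised by their selection against the shared baseline. Library size moved the median of all genes to at most 0.0181 and at least -0.0331 on the log2 scale.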

Other observations

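The gene families below were chosen only after their values were seen, while the test on NAD synthesis genes was fixed before its result was seen. As NMRK2 and NAMPT both act in NAD salvage, a rise of NAD synthesis genes as a group in the 4-set legs was tested as a hypothesis. The other 10 NAD genes differed between the legs by 0.029 (SE 0.0201, sign-flip permutation p = 0.159, 6 of 10 above 0), so a rise of the group was not shown and the difference may be limited to NMRK2 and NAMPT.

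Of 11 genes of SR splicing factors (SRSF), 4 were lower with 4 sets than at baseline and all 11 lay below 0, with a mean paired difference of -0.107 (SE 0.0225); with 1 set the mean was -0.0737 (SE 0.0196) and between the legs -0.0331 (SE 0.0169). Of 22 hnRNP genes, 4 were lower with 4 sets and 21 lay below 0, with a mean of -0.0721 (SE 0.0169), beside -0.055 with 1 set and -0.0171 between the legs. As both families were picked for these values, no p is given for them. With 4 sets 7 of 17 ATP synthase genes (ATP5), 2 of 12 SLC16A and 3 of 43 SLC25A genes were higher, and 2 of 15 KLF genes were lower. SFPQ, another splicing factor, fell by 0.19 on the log2 scale (adjusted p = 0.000191). Of single genes of the malate-aspartate shuttle, picked after their values were seen and not tested as a group, SLC25A12 differed between 4 sets and baseline by 0.23 ± 0.04 SE (adjusted p = 3.7e-05), GOT1 by 0.27 ± 0.05 (adjusted p = 0.00139) and GOT2 by 0.26 ± 0.05 (adjusted p = 0.00333).

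The 9 clock genes of the PER and NR1D arm varied widely between visits and little between the legs of 1 visit. The SD of the paired differences over 27 participants was 1.11 for 1 set against baseline, 1.08 for 4 sets against baseline and 0.114 between the legs.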
